A study of Homo sapiens with 6 samples.

How the data were processed

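The samples were human T cells positive for CD3, sorted by flow cytometry after 48 h of culture of 1200000 blood mononuclear cells with 100000 MDA-MB-231 cells. Of the 6 libraries, 3 came from cultures given 4 nM of a bispecific T cell engager (BiTE) built on the 4D5 antibody and 3 from cultures given 4 nM of the same engager joined to a sialidase. Groups and replicate numbers were taken from the sample titles. Per the labels' protocols, total RNA was isolated with a column kit for small samples and libraries were made from polyadenylated RNA.

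The deposited values were normalised counts per gene (unit signal), 1 table with 60671 rows for the 6 libraries and 0 rows that named no gene. Per the submitters' processing notes, bcl2fastq, STAR 2.7.0f, DESeq2 and the GRCh38 build were used, with no order or role stated. The read counter, the annotation release, the strand setting and any filter were not given in the sources used here. In each library, 100% of the deposited signal values were whole multiples of the smallest value above 0, within a tolerance of 0.01 reads, so reads per gene could be recovered by division by that step. For BiTE replicate 3 the step lay within about 1% of 1, and the recovery was not decided by the automatic check of the unit. Recovered reads came to 16299009, 18207709 and 17229775 in BiTE replicates 1 to 3 and to 16177016, 22409165 and 19176246 in BiTE-sialidase replicates 1 to 3. The deposited normalised counts added up to between 17379141 and 17629540 in the BiTE libraries and between 18292369 and 18557152 in the BiTE-sialidase libraries.

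Genes with a mean of at least 10 normalised counts over the 6 libraries were kept, which left 16026. Because the values were not raw counts, the test was limma 3.58.1 in R 4.3.3, with a mean-variance trend, on log2(normalised count + 1). Differences were BiTE-sialidase minus BiTE, two-sided, with no covariate, and p-values were adjusted by the Benjamini-Hochberg method over all genes kept, with a threshold of 0.05. Fold changes are on the log2(value + 1) scale, which understates the change of genes with low values. The median standard error of a log2 fold change was 0.14. Gene lists were tested with limma's camera with a preset correlation between genes of 0.01 over the 35 lists that kept at least 5 genes, and again with an estimated correlation and with fry, a rotation test of whether the genes of a list move one way. Members of each list were also adjusted over the list alone. The ratio of CD4 to CD8A was compared with an exact two-sided permutation test, whose smallest possible p with 3 libraries against 3 is 0.1.

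The groups, the test, the 40 gene lists, the rule for named genes and all alternatives except 3 were chosen before the data were examined. The rule named the 8 largest rises and 8 largest falls among genes past the threshold with a mean of at least 50 normalised counts and no overlap between groups. It added, from each list, the 4 members with the smallest p (or, where none passed, the 2 with the highest mean), and a fixed set of 15 T cell genes. XIST and Y-linked genes, variable segments of antigen receptors, genes whose presence varies between people and rows with no symbol were left out, and 3 genes picked by the rule are not reported here. Any other gene named below was chosen after its values were seen.

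Gene symbols are those of the deposited table, and 38076 of its rows, 13952 of them among the genes tested, matched the GENCODE v29 annotation of GRCh38, from which positions, GC content and transcript lengths were taken. The match went through a table of gene names and used current symbols only. Genes with no match were left unchanged where a GC and length trend was removed. HSPA1A and HSPA1B are near-identical copies, and how reads were divided between them is not known. Reads of overlapping genes on opposite strands could not be told apart, since the strand setting was not given.

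Alternatives were a pseudocount of 0.5 or 8, no filter, a minimum mean of 50, equal library totals, quantile normalisation, robust variances, library quality weights, edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads, the replicate number as a block, and leaving out each library in turn. The alternatives added after seeing the data were the mean log2 level of the tumour marker list as a covariate, removal of a GC and length trend from each library, and leaving out the genes of the tumour and other cell type lists. On simulated data with 200 changed genes among 16026, drawn for this comparison, limma recovered 46.3% of the genes changed by 0.5 on the log2 scale, 62.7% of those changed by 1 and 95.5% of those changed by 2, with 10 false calls. More genes were called in the real data, and the adjusted threshold depends on the share of changed genes. These rates may therefore not hold for the real data. Figures were drawn with matplotlib.

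The libraries were compared before averaging. Chi-square per degree of freedom between recovered reads lay between 4.17 and 13 within groups, so no pair was a repeat of one library. The series describes the libraries as biological replicates, but whether they came from separate donors is not stated, so the p-values measure the spread between these 6 samples, which may be technical.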

Results

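Bispecific T cell engagers are fusion proteins that bind CD3 on T cells and an antigen on tumour cells. The engager studied here carried 4D5, an antibody against HER2, and was used alone (BiTE) or joined to a sialidase, an enzyme that removes sialic acid from cell surface glycans (BiTE-sialidase). Each was added at 4 nM to cultures of 1200000 human blood mononuclear cells and 100000 cells of MDA-MB-231, a breast cancer line, and CD3-positive T cells were sorted after 48 h for bulk RNA sequencing. There were 3 libraries per group, with between 16177016 and 22409165 recovered reads each. Transcripts of the mitochondrial genome took between 6.31% and 6.82% of the normalised counts. Across genes, Pearson's r of log2 values lay between 0.975 and 0.985 within groups and between 0.966 and 0.977 between groups, where genes are not independent replicates. BiTE replicate 1 had the lowest mean r with its own group, 0.976.

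The comparison asked how the transcripts of T cells differed when the engager carried a sialidase. T cells from cultures with BiTE-sialidase had higher transcripts of interferon gamma, of granzyme B and of the high-affinity IL-2 receptor chain, while cytokine genes as a whole moved both ways. Lists of protein folding, ribosome biogenesis and DNA replication genes passed as higher with limma's camera, but not with an estimated correlation between genes. IFNG, the main cytokine of type 1 responses, rose 4.32-fold, from 570.5 ± 169.0 to 2483 ± 883 normalised counts (SD, n = 3 per group). GZMB, a protease of cytotoxic granules, rose 3.08-fold, from 19910 ± 2306 to 61093 ± 2071. IL2RA, the alpha chain of the IL-2 receptor, rose 1.84-fold, from 10552 ± 415 to 19383 ± 361. TCF7, a transcription factor of naive and memory T cells, fell 1.61-fold, from 13715 ± 1173 to 8482 ± 110, and 21 of 37 markers of MDA-MB-231 and epithelial tumour cells fell, with a list mean log2 fold change of −1.07. That list passed as lower with camera, but not with an estimated correlation (Benjamini-Hochberg adjusted p = 0.0841).

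With limma and Benjamini-Hochberg adjustment, 1866 of 16026 genes were higher and 1383 lower with BiTE-sialidase at an adjusted p under 0.05. Changes of at least 2-fold were seen for 98 of the higher and 314 of the lower genes. The values of the 3 libraries of one group did not overlap those of the other for 36.3% of genes, against 10% by chance. When the libraries were rescaled to equal totals, 1146 genes were higher and 1972 lower. With library quality weights 2716 were higher and 2107 lower, and after GC and length correction 2823 were higher. The count of higher genes was 1233 without BiTE-sialidase replicate 1 and 1117 without BiTE-sialidase replicate 2, and the count of lower genes was 911 without BiTE-sialidase replicate 2. Of 35 gene lists fixed beforehand and tested with limma's camera, 15 passed as higher and 5 as lower, whereas 0 passed with an estimated correlation, of which 10 had an unadjusted p under 0.05, and 28 passed with fry. In splits of the libraries that mixed the groups, with 0 genes called, camera with the preset correlation still passed 5 to 13 lists. Part of the group difference stayed in those splits, so they give no rate of false calls.

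Genes on the tumour marker list differed between the sorted samples. The mean log2 level of the fixed tumour marker list lay between 6.52 and 6.83 in BiTE and between 5.44 and 5.69 in BiTE-sialidase libraries. Within each group this mean fell with the replicate number, whereas that of the heat shock list rose. The tumour list mean was 6.829, 6.524 and 6.515 in BiTE and 5.687, 5.525 and 5.437 in BiTE-sialidase libraries. With that mean as a covariate, an alternative added after seeing the data and almost inseparable from the group, 378 genes were higher, 353 were lower and 8 lists passed. Lists that lost their call in that fit were those of heat shock, early transcription factors, activation surface proteins, cytokines and chemokines, the IL-2 and STAT5 response, naive and memory genes, T helper 2 genes and CD4 markers. The interferon gamma, oxidative phosphorylation, ribosomal protein, monocyte and dendritic cell lists lost it too, as did the tumour list, by construction. IFNG, IL21, LTA, GZMB, IL2RA, HSPA8 and TCF7 were among the genes still past the threshold in that fit. HSPA1A, HSPA1B, BATF3, TBX21, IL5, CD69, LAG3, CXCL11, IL6, IFIT2, PTPRC, CD3G, LYZ, TIMP3, A2M and TGM2 were not, and had the opposite sign. Of the 139 genes named by rule, 66 lost the call without a change of sign in that fit, and 31 reversed.

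**Figure D1:**
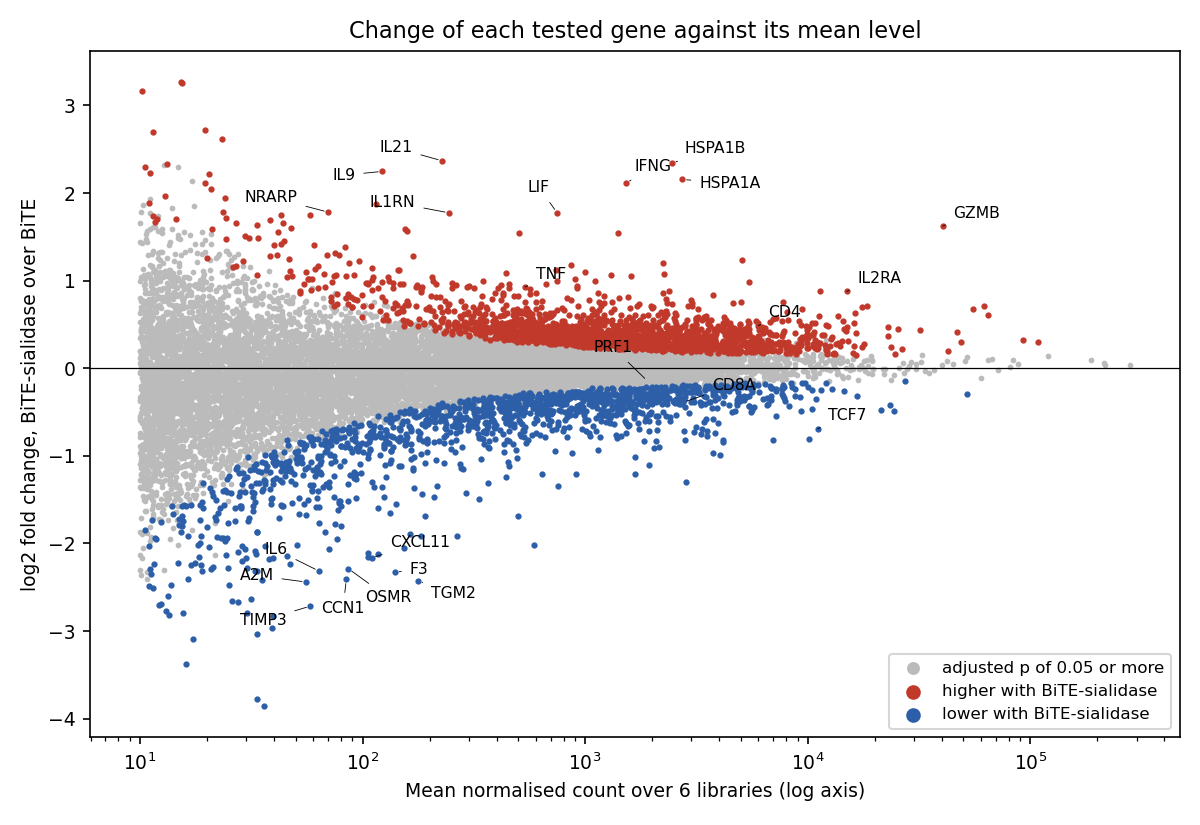
Log2 fold change (BiTE-sialidase over BiTE) of the tested genes, with XIST and Y-linked genes left out, against their mean normalised count over 6 libraries, on a log axis; red points are the 1866 genes higher and blue points the 1383 genes lower at an adjusted p under 0.05 (limma, Benjamini-Hochberg). GZMB stands apart among abundant genes at 1.62, while the largest falls, such as TIMP3 at −2.72, lie among genes of low level.

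Cytokine genes moved in both directions. Among 31 measured T cell cytokines and chemokines, 9 rose, 6 fell and 16 did not pass; adjusted over the list alone, 11 rose and 7 fell. The list passed as higher (limma camera, Benjamini-Hochberg adjusted p = 0.0122, and adjusted p = 0.165 with an estimated correlation), a call also lost with a minimum mean of 50, after GC and length correction and with the tumour marker covariate. The largest rise of any gene under the naming rule was that of IL21, a cytokine of follicular helper T cells, with a log2 fold change of 2.37 (SE 0.28, limma, Benjamini-Hochberg adjusted p = 1.92e-05), from 77.6 ± 39.2 to 378 ± 94.7 normalised counts. IFNG had a log2 fold change of 2.11 (SE 0.20, limma, Benjamini-Hochberg adjusted p = 2.59e-06) and lies on chromosome 12 (GRCh38, 68154768 to 68159747, minus strand, protein-coding). IL9, a cytokine of mast cell responses, rose by 2.25 on the log2 scale, LIF, a cytokine of the IL-6 family, by 1.77, LTA (lymphotoxin alpha) by 1.54, and TNF by 0.93, from 370.6 ± 31.5 to 705 ± 52.6 normalised counts. IL9, LIF and TNF each passed under 19 of 20 alternative settings, with lowest values of 1.25, 1.15 and 0.32. IL2, the T cell growth factor, was barely detected, at 8.0 ± 6.6 and 19.4 ± 5.49 normalised counts (log2 fold change 1.44, limma, Benjamini-Hochberg adjusted p = 0.127). IL2 log2 fold change passed without BiTE replicate 3, at 2.01. IL17A, the cytokine that defines T helper 17 cells, fell by 2.83 on the log2 scale, from 70.1 ± 23.7 to 9.31 ± 5.18 normalised counts, and IL6, an inflammatory cytokine, fell by 2.32. In the same libraries the tumour marker list and the monocyte list, with mean log2 fold changes of −1.07 and −0.94, were also lower. Not all members of either list fell.

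Genes induced through the T cell receptor were mostly higher. Of 34 early transcription factors and feedback genes of T cell receptor signalling, 19 rose and 2 fell, with 13 not passing, and 23 rose and 2 fell adjusted over the list alone. The list passed as higher (limma camera, Benjamini-Hochberg adjusted p = 5.34e-08, and adjusted p = 0.179 with an estimated correlation). Examples were DUSP5, a phosphatase that restrains ERK, at a log2 fold change of 1.08, FOSB, a subunit of AP-1, at 0.99, and BATF3, another AP-1 family member, at 1.17. The 2 that fell were RGS1, at −0.54, and EGR3, at −0.85. FOSB rose with the replicate number within each group, from 3318 to 4132 in BiTE and from 6352 to 8142 in BiTE-sialidase libraries. HSPA1A, of the heat shock list, did so too, and whether handling raised genes of this list was not tested. FOSB passed under 19 of 20 alternative settings, with a lowest value of 0.005. The mean of the list changed sign with the tumour marker covariate. Among 25 surface proteins of activation, 13 rose and 4 fell (13 and 5 adjusted over the list alone), and the list passed (limma camera, Benjamini-Hochberg adjusted p = 0.00145, and adjusted p = 0.0841 with an estimated correlation), a call also lost with the tumour marker covariate. IL2RA had a log2 fold change of 0.88 (SE 0.05, limma, Benjamini-Hochberg adjusted p = 2.24e-08), and CD40LG, the ligand through which helper T cells activate other cells, rose by 1.12. CD69, an early activation marker, had a log2 fold change of 0.27 that passed under 14 of 20 alternative settings and lost its call without BiTE replicate 2, BiTE-sialidase replicate 2 or BiTE-sialidase replicate 3. TNFRSF9 (4-1BB), a costimulatory receptor, did not pass, at −0.07. Of 29 genes of the IL-2 and STAT5 response, 14 rose and 3 fell (15 and 3 adjusted over the list alone), with CCND3, a G1 cyclin, at 0.76 (limma camera, Benjamini-Hochberg adjusted p = 2.45e-05, and adjusted p = 0.179 with an estimated correlation). The mean of that list also changed sign with the tumour marker covariate. Of its members 13 were also on another list, as were 15 of the 31 cytokines and chemokines and 12 of the 25 surface proteins. The calls on these lists were thus not independent.

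**Figure D2:**
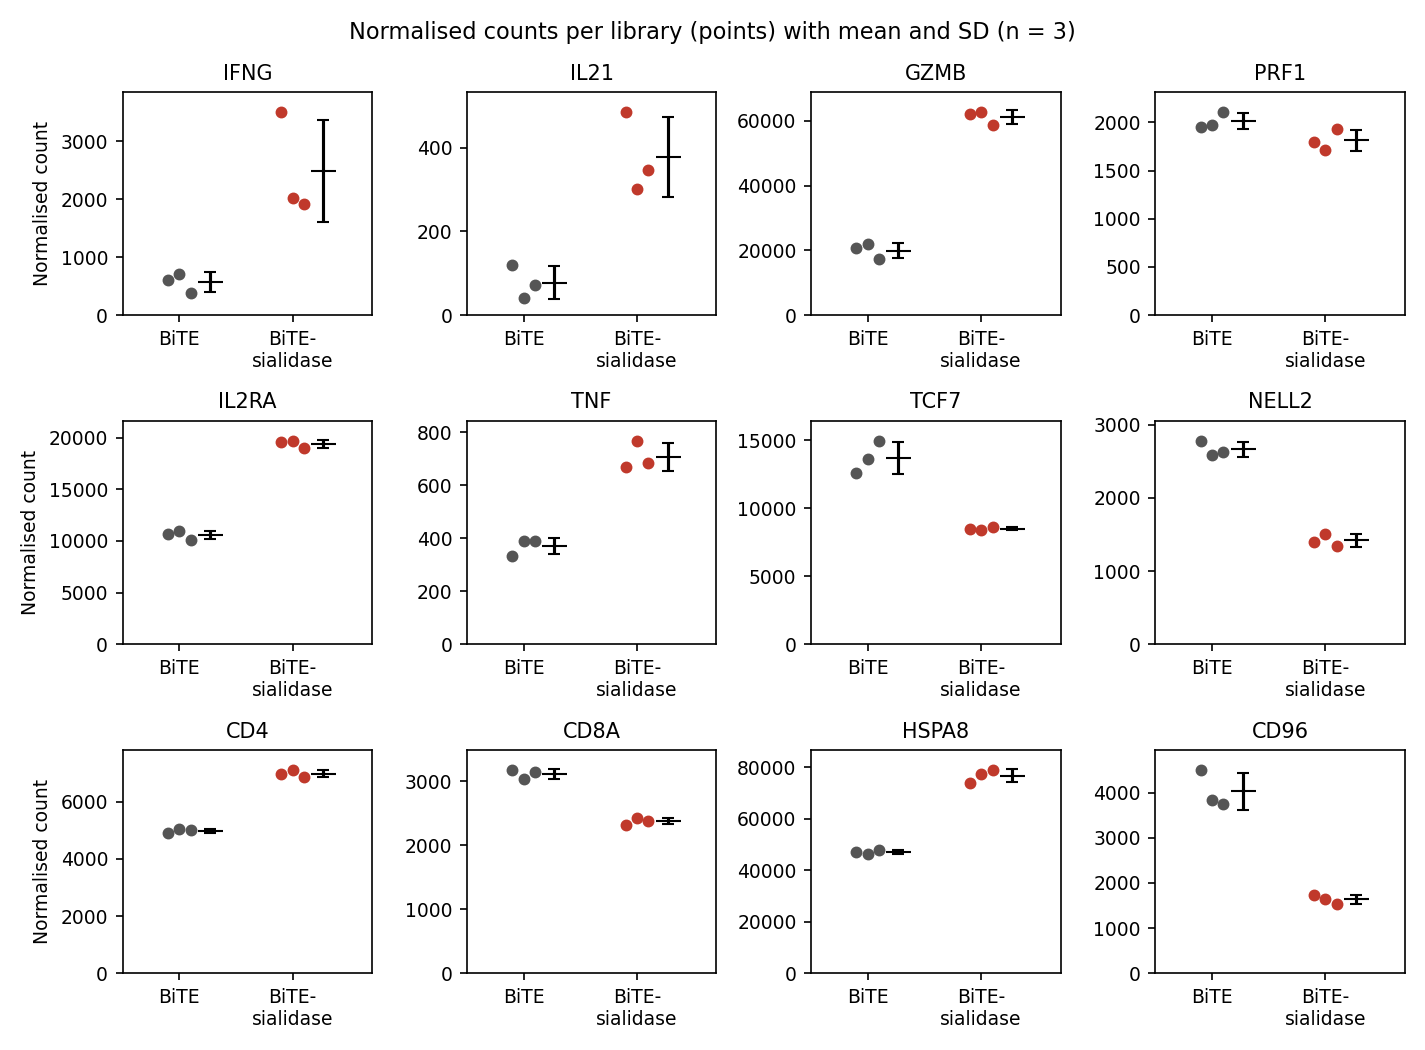
Normalised counts of 12 genes in each library (points, 3 per group) with the mean and SD beside them, each panel on its own linear axis from 0. GZMB, IFNG, IL21 and IL2RA are higher and TCF7, NELL2, CD8A and CD96 lower in all 3 BiTE-sialidase libraries than in any BiTE library; PRF1 did not pass the test.

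Cytotoxic genes did not pass as a list with camera, and granzyme B stood out. Of 30 cytotoxic granule and killing genes, 8 rose, 4 fell and 18 did not pass (10 and 5 adjusted over the list alone), and the list did not pass (limma camera, Benjamini-Hochberg adjusted p = 0.313), although it passed as higher with fry (Benjamini-Hochberg adjusted p = 0.0160). GZMB, on chromosome 14 (24630954 to 24634267, minus strand, protein-coding), had a log2 fold change of 1.62 (SE 0.07, limma, Benjamini-Hochberg adjusted p = 3.54e-10). NKG7, a granule membrane protein, rose by 0.66 and TBX21, the T-bet transcription factor, by 0.61, whereas KLRG1, a receptor of terminal effector cells, fell by 0.95. NKG7 and KLRG1 each passed under 19 of 20 alternative settings, with smallest changes of 0.21 and −0.44. PRF1 (perforin), the pore-forming partner of granzymes, was at 2010 ± 82 and 1814 ± 108 normalised counts (log2 fold change −0.15, limma, Benjamini-Hochberg adjusted p = 0.164). PRF1 log2 fold change passed as lower with equal totals, at −0.23, and after GC and length correction, at −0.22. Of 17 natural killer cell markers, 1 rose and 1 fell, the same adjusted over the list alone, and the list did not pass (limma camera, Benjamini-Hochberg adjusted p = 0.643).

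The balance of CD4 and CD8 transcripts differed between the groups. CD4, the coreceptor of helper T cells, rose by 0.49 on the log2 scale, while CD8A and CD8B, the chains of the cytotoxic coreceptor, fell by 0.39 and 0.49. The ratio of CD4 to CD8A normalised counts was 1.60 ± 0.058 in BiTE and 2.94 ± 0.065 in BiTE-sialidase libraries (SD, n = 3, exact two-sided permutation p = 0.1, the smallest that 3 against 3 allows). Of 9 CD4 T cell markers, 4 rose and 2 fell, also when adjusted over the list alone (limma camera, Benjamini-Hochberg adjusted p = 0.0474, and adjusted p = 0.179 with an estimated correlation), a call that was lost with a minimum mean of 50, equal totals, quantile normalisation and the tumour marker covariate, and without BiTE replicate 2 or BiTE-sialidase replicate 3. Of 4 CD8 T cell markers, 0 rose and 3 fell, and of 4 gamma delta T cell markers 1 fell, with the same counts adjusted over each list alone; both lists were too small for camera. Helper subsets were mixed. T helper 1 genes split into 7 higher and 5 lower of 15, the same adjusted over the list alone, with a mean of 0.23, a median of −0.07 and no call (limma camera, Benjamini-Hochberg adjusted p = 0.310), although they passed as higher with no filter, DESeq2 and fry. T helper 2 genes had 4 higher and 1 lower of 12, the same adjusted over the list alone, among them IL5, the eosinophil growth factor, at 1.42 (limma camera, Benjamini-Hochberg adjusted p = 0.0469, and adjusted p = 0.179 with an estimated correlation). That call was lost without BiTE replicate 1, BiTE replicate 2, BiTE-sialidase replicate 1 or BiTE-sialidase replicate 3. It was also lost with a minimum mean of 50, quantile normalisation, GC and length correction and the tumour marker covariate. T helper 17 genes had 0 higher and 3 lower of 11, the same adjusted over the list alone (limma camera, Benjamini-Hochberg adjusted p = 0.0919), and passed as lower with fry. Of the helper lists, only T helper 2 genes passed in the main test, and the ratio of CD4 to CD8A differed in the same libraries.

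Genes of naive and memory T cells were lower on balance. Of 28 members, 10 fell and 4 rose (12 and 6 adjusted over the list alone), and the list passed as lower (limma camera, Benjamini-Hochberg adjusted p = 7.93e-05, and adjusted p = 0.0914 with an estimated correlation), a call also lost with the tumour marker covariate. TCF7 fell by 0.69 (SE 0.06, limma, Benjamini-Hochberg adjusted p = 1.22e-06), its partner LEF1 by 0.70, and PIK3IP1, a brake on PI3 kinase, by 0.90. CCR7, the lymph node homing receptor, did not pass, at 14729 ± 480 and 13812 ± 653 normalised counts, but passed as lower with equal totals, quantile normalisation and GC and length correction. Of 37 genes of the T cell receptor complex and synapse, 15 fell and 3 rose, the same adjusted over the list alone (limma camera, Benjamini-Hochberg adjusted p = 0.00145, and adjusted p = 0.250 with an estimated correlation), with CD5 and CD6, inhibitory scavenger receptors, at −0.48 and −0.49 and CD3G, a chain of CD3, at −0.50. Inhibitory receptors went both ways, with 4 higher and 6 lower of 22 (4 and 9 adjusted over the list alone), and did not pass (limma camera, Benjamini-Hochberg adjusted p = 0.0712), although they passed as lower with no filter, DESeq2 and fry. HAVCR2 (TIM-3) rose by 0.61, CTLA4 by 0.44, CD274 (PD-L1) by 0.70 and LAG3 by 0.37, while CD96, a receptor for nectin-like ligands, fell by 1.29 from 4028 ± 406 to 1639 ± 95.9 normalised counts. PDCD1 (PD-1) was at 927 ± 218 and 909 ± 88.4 normalised counts and did not pass, although PDCD1 log2 fold change passed as lower with the tumour marker covariate, at −1.75.

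Lists of growth and metabolic genes passed as higher by small amounts, though none with an estimated correlation, and in some of them most members did not pass. Of 40 DNA replication genes 29 rose and 0 fell (32 and 0 adjusted over the list alone), among them CDC6, a loader of the replicative helicase, at a log2 fold change of 0.71 (limma camera, Benjamini-Hochberg adjusted p = 7.74e-17, and adjusted p = 0.0769 with an estimated correlation). Mitotic genes did not follow, with 2 higher and 4 lower of 39, the same adjusted over the list alone (limma camera, Benjamini-Hochberg adjusted p = 0.313), although the list passed as lower with quantile normalisation and without BiTE replicate 3. MKI67, a marker of cycling cells, was at 11599 ± 570 and 11636 ± 130 normalised counts and did not pass, although after GC and length correction it passed as higher. Of 35 ribosome biogenesis genes 27 rose (29 adjusted over the list alone) and 0 fell, with NCL (nucleolin) at 0.47 (limma camera, Benjamini-Hochberg adjusted p = 1.39e-17, and adjusted p = 0.0769 with an estimated correlation). Of 25 glycolysis genes 17 rose and 0 fell (18 and 1 adjusted over the list alone), with HK2, the inducible hexokinase, at 0.76 (limma camera, Benjamini-Hochberg adjusted p = 5.18e-10, and adjusted p = 0.0841 with an estimated correlation). Of 54 nuclear genes of oxidative phosphorylation 13 rose and 0 fell, the same adjusted over the list alone, with CYCS (cytochrome c) at 0.55 (limma camera, Benjamini-Hochberg adjusted p = 0.000125, and adjusted p = 0.0769 with an estimated correlation), a call also lost with the tumour marker covariate. Ribosomal protein genes had 7 higher of 72 (1 adjusted over the list alone), and their mean of 0.07 turned to −0.03 under quantile normalisation and lost its call with equal totals, without BiTE replicate 2 and without BiTE-sialidase replicate 2 (limma camera, Benjamini-Hochberg adjusted p = 0.0242, and adjusted p = 0.566 with an estimated correlation). That call was also lost with a minimum mean of 50, DESeq2, GC and length correction, the tumour marker covariate and fry.

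All 22 measured heat shock and handling stress genes rose, also when adjusted over the list alone (limma camera, Benjamini-Hochberg adjusted p = 2.02e-23, and adjusted p = 0.0841 with an estimated correlation). With the tumour marker covariate the list lost its call, and its mean went from 0.83 to −0.10. HSPA8, the constitutive HSP70 chaperone, rose 1.63-fold from 46969 ± 733 to 76663 ± 2441 normalised counts, and HSP90AA1, the inducible HSP90, by 0.67 on the log2 scale. The near-identical stress-induced copies HSPA1A and HSPA1B rose by 2.15 and 2.34, with an uncertain division of shared reads between them. Of 26 genes of endoplasmic reticulum stress and folding 16 rose and 0 fell (18 and 1 adjusted over the list alone), with CALR (calreticulin) at 0.47 (limma camera, Benjamini-Hochberg adjusted p = 1.70e-11, and adjusted p = 0.160 with an estimated correlation). Of 23 genes of the ATF4 amino acid response 16 rose and 0 fell (19 and 0 adjusted over the list alone), with SLC7A5, a transporter of large neutral amino acids, at 0.54 (limma camera, Benjamini-Hochberg adjusted p = 9.75e-13, and adjusted p = 0.0769 with an estimated correlation).

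Although IFNG rose, genes of the interferon gamma response were more often lower. Of 42 members 13 fell and 7 rose (15 and 8 adjusted over the list alone), and the list passed as lower (limma camera, Benjamini-Hochberg adjusted p = 0.0469, and adjusted p = 0.179 with an estimated correlation), a call that was lost with library quality weights, with the tumour marker covariate, and without BiTE replicate 3 or BiTE-sialidase replicate 1. GBP5, an interferon-induced GTPase, fell by 0.84, from 5331 ± 143 to 2968 ± 23.9 normalised counts, and CXCL11, a chemokine for CXCR3, by 2.16, whereas WARS1, a tryptophan tRNA ligase, rose by 0.65. The monocyte list had a mean log2 fold change of −0.94 in the same libraries, although not all of its members fell. Type I interferon genes had 6 higher and 10 lower of 41 (7 and 11 adjusted over the list alone) and did not pass (limma camera, Benjamini-Hochberg adjusted p = 0.154), although they passed as lower with quantile normalisation and fry, with TRIM22, an antiviral factor, lower by a log2 value of −1.21 and IFIT2 higher by 0.96.

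Genes that build or bind sialic acid were mostly not past the threshold. Of 21 genes of sialic acid synthesis and sialyltransfer, 2 rose and 4 fell, the same adjusted over the list alone (limma camera, Benjamini-Hochberg adjusted p = 0.256), and the list passed as lower with fry. ST3GAL5, which makes the ganglioside GM3, fell by 0.86, and ST3GAL4, which caps glycoprotein galactose, rose by 0.82. Of 30 glycocalyx core proteins and O-glycan enzymes, 6 rose and 4 fell (6 and 5 adjusted over the list alone), with a mean of −0.05, a median of 0.05 and no call (limma camera, Benjamini-Hochberg adjusted p = 0.817), although they passed as higher with the tumour marker covariate. GCNT1, which starts core-2 O-glycan branches, rose by 1.07, and PTPRC (CD45), a heavily sialylated phosphatase, fell by 0.48. Of 4 measured sialic acid binding receptors, too few for camera, 1 rose, also adjusted over the list alone: SIGLEC12, at 9.51 ± 4.28 and 38.9 ± 13 normalised counts, a call lost without BiTE-sialidase replicate 2 or 3.

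Marker genes of other cell types also differed between the sorted samples. Of 37 measured markers of MDA-MB-231 and epithelial tumour cells, 21 fell and 1 rose (23 and 1 adjusted over the list alone), and the list passed as lower (limma camera, Benjamini-Hochberg adjusted p = 8.71e-11, and adjusted p = 0.0841 with an estimated correlation). The largest falls of any gene under the naming rule were those of TIMP3, an inhibitor of metalloproteinases (−2.72), A2M, a protease inhibitor (−2.44), TGM2, a transglutaminase (−2.43), CCN1, a matricellular protein (−2.41), and F3, tissue factor (−2.33). CCN1 and F3 are on the tumour marker list, whereas TIMP3, A2M and TGM2 are on neither that list nor the monocyte list. Of 14 monocyte and macrophage markers 6 fell and 0 rose, the same adjusted over the list alone (limma camera, Benjamini-Hochberg adjusted p = 0.00145, and adjusted p = 0.0841 with an estimated correlation), a call also lost with the tumour marker covariate, with LYZ (lysozyme) at 48.1 ± 21 and 7.20 ± 4.51 normalised counts. CD14, AIF1 and FCER1G, on the same list, did not pass and had log2 fold changes above 0 (0.10, 0.33 and 0.52). Whether the number of monocytes differed was not measured. Of 7 dendritic cell markers 3 rose (4 adjusted over the list alone), namely GZMB, BATF3 and CCL17, of which GZMB and BATF3 are also made by activated T cells (limma camera, Benjamini-Hochberg adjusted p = 0.00186, and adjusted p = 0.186 with an estimated correlation), a call also lost with the tumour marker covariate. The call on CCL17 was lost without BiTE-sialidase replicate 1.

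**Figure D3:**
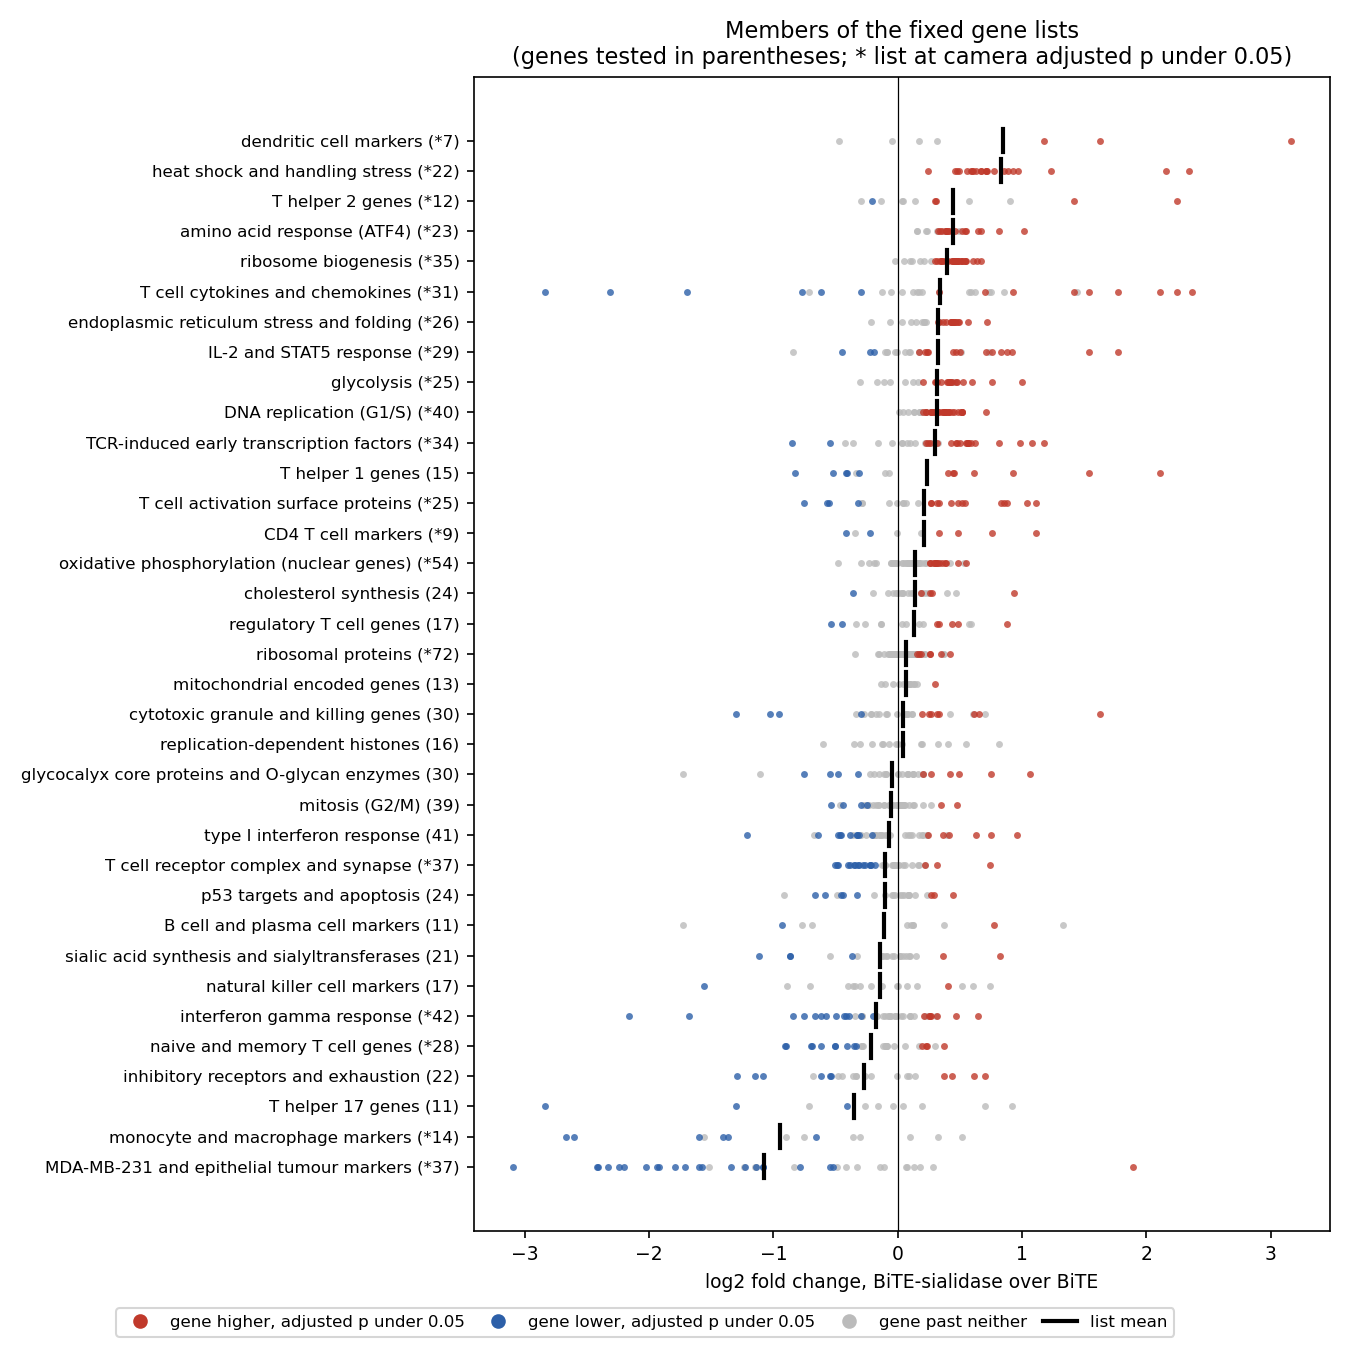
Log2 fold change (BiTE-sialidase over BiTE) of every tested member of the 35 fixed gene lists with at least 5 tested genes, with red and blue points for genes higher or lower at an adjusted p under 0.05 (limma, Benjamini-Hochberg), grey points for the rest and a black bar for the list mean. The heat shock list has all 22 genes to the right of 0, and the tumour marker list has its mean at −1.07.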

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

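The tumour marker covariate, the GC and length correction and the removal of other cell type genes were chosen after the results were seen. The genes named kept direction and side of the threshold in 2575 of 2754 comparisons with an alternative, lost the call in 139, gained one in 9 and reversed in 31, and 15 further sign changes stayed below the threshold. For the gene lists, where direction was that of camera and not the sign of the mean, these counts were 646 of 733, 55, 27, 5 and 18. Genes higher numbered 1146 with equal totals, 2823 after GC and length correction and between 1117 and 2257 when 1 library was left out (1233 without BiTE-sialidase replicate 1, 1117 without BiTE-sialidase replicate 2). Genes lower numbered 2107 with library quality weights and between 911 and 1527 when 1 library was left out (911 without BiTE-sialidase replicate 2). With edgeR on the recovered reads, 1800 genes were higher and 1423 lower, and with DESeq2 1814 and 1495. With an estimated correlation, 0 lists passed, 10 at an unadjusted p. Deposited totals were higher in the BiTE-sialidase than in the BiTE libraries, so equal totals lowered the log2 fold changes. The cause of the other moves was not tested. Simulated changes of 0.5 on the log2 scale were recovered for 46.3% of genes, with a smaller share of changed genes than was called in the data. Neither that share nor depth nor the number of libraries was varied.

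Across genes, same-numbered libraries did not deviate together (correlations of deviations between −0.02 and 0.05). Not every library correlated best with its own number (BiTE replicate 2 with BiTE-sialidase replicate 2 was at −0.02). No pairing by number was thus seen across genes. HSPA1A however rose with the number in both groups (676, 849 and 1546 in BiTE, 3182, 3980 and 6198 in BiTE-sialidase libraries). Whether the numbers pair the samples was therefore not settled. With the replicate number as a block, 2377 genes were higher and 1684 lower, and 20 lists passed, 19 of them as in the main fit, with mitochondrially encoded genes added and T helper 2 genes not past the threshold.

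With the tumour marker covariate, 378 genes were higher, 353 lower and 8 lists passed, and the covariate did not overlap between groups, so the fit hardly separates it from the treatment. The covariate also fell with the replicate number within each group, whereas HSPA1A and the mean of the heat shock list rose. The cause of the reversals was not tested. Signs reversed for HSPA1B (−0.24), HSPA1A (−0.94), TIMP3 (0.37), A2M (0.73), TGM2 (0.21), IL6 (0.86), CXCL11 (1.42), BATF3 (−0.17), TBX21 (−0.043), MAF (−0.062), IL5 (−0.38), GATA3 (−0.42), RORA (0.35), KLRB1 (1.24), CDT1 (−0.12), TOP2A (0.26), CKS2 (−0.10), CDC20 (−0.11), IFIT2 (−0.51), NDUFB10 (−0.22), RPS24 (−0.14), RPL8 (−0.83), RPL36 (−1.28), PTPRC (0.10), CD3G (0.094), TRGC1 (0.59), IL1B (1.23), LYZ (0.66), MT-CO3 (−0.20), CD69 (−0.39) and LAG3 (−0.13), of which RPL8 and RPL36 alone passed as lower. Among lists, the early transcription factors turned to −0.34, the IL-2 and STAT5 response to −0.056 and ribosomal proteins to −0.18, each without a call. Heat shock genes turned to −0.10, CD4 markers to −0.019 and monocyte markers to 0.066, also without a call. The glycocalyx list turned to 0.34 and passed, and T helper 2 genes kept a mean of 0.37 while camera's direction turned. The ribosomal protein mean was −0.025 under quantile normalisation and −0.010 with equal totals.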

Other observations

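The scan of gene families and the tests of KRT18, of CD8 and natural killer cell markers and of other splits were chosen after the results were seen. Gene families that share a symbol stem gave a view of biology outside the fixed lists. Of 151 families with at least 10 tested genes, 22 were higher and 7 lower with BiTE-sialidase (limma camera, Benjamini-Hochberg), 24 of these also with equal totals, and 0 with an estimated correlation, of which 21 had an unadjusted p under 0.05. Among 53 translation initiation factors of the EIF family 23 rose and 0 fell (limma camera, Benjamini-Hochberg adjusted p = 3.68e-07, and adjusted p = 0.316 with an estimated correlation). Proteins of the large mitochondrial ribosomal subunit (MRPL) had 21 higher of 48 and inner membrane import proteins (TIMM) 8 of 15. Proteasome subunits were higher in both parts of the complex, with 9 of 14 PSMD and 7 of 10 PSMB genes. Each of these 4 families passed (limma camera, Benjamini-Hochberg adjusted p of at most 0.000772), and none with an estimated correlation (adjusted p between 0.280 and 0.352). In the other direction, 8 of 10 chemokines of the CXCL family fell, with a median log2 fold change of −1.25 (limma camera, Benjamini-Hochberg adjusted p = 1.46e-06, and adjusted p = 0.316 with an estimated correlation). The means of the monocyte and tumour marker lists were also lower in these libraries, at −0.94 and −1.07, though neither list passed with an estimated correlation. CXCL5 is on the monocyte list, and CXCL11 log2 fold change turned to 1.42 with the tumour marker covariate. Of 451 zinc finger genes of the ZNF family 53 fell and 11 rose, with a median of −0.17 (limma camera, Benjamini-Hochberg adjusted p = 0.000213, and adjusted p = 0.280 with an estimated correlation).

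The remaining fixed lists did not pass in the main test. Regulatory T cell genes had 5 higher and 2 lower of 17 (5 and 3 adjusted over the list alone, limma camera, Benjamini-Hochberg adjusted p = 0.154), and passed as higher with no filter, DESeq2 and fry. FOXP3 was among the higher genes, at a log2 fold change of 0.48, and IKZF4, a partner of FOXP3, among the lower, at −0.45. Cholesterol synthesis had 4 higher and 1 lower of 24 (5 and 1 adjusted over the list alone, limma camera, Benjamini-Hochberg adjusted p = 0.0852), led by NSDHL, a sterol dehydrogenase, at 0.93, and passed as higher with no filter and fry. The p53 and apoptosis genes had 3 higher and 5 lower of 24, the same adjusted over the list alone (limma camera, Benjamini-Hochberg adjusted p = 0.566), with TP53INP1 at −0.67 and PMAIP1 (NOXA) at 0.45. Of 11 B cell and plasma cell markers 1 rose and 1 fell, the same adjusted over the list alone, with a mean of −0.11 and a median of 0.11 (limma camera, Benjamini-Hochberg adjusted p = 0.757). Of 13 mitochondrially encoded genes 1 rose, MT-CO3, also adjusted over the list alone (limma camera, Benjamini-Hochberg adjusted p = 0.0686), a call on the gene that was lost under quantile normalisation. That list passed as higher with no filter, library quality weights, edgeR, the tumour marker covariate and fry, and without BiTE replicate 1 or BiTE-sialidase replicate 3. Of 16 replication-dependent histone genes none passed, with a mean of 0.04 and a median of −0.01 (limma camera, Benjamini-Hochberg adjusted p = 0.970). Their group means were at most 156 normalised counts. The libraries were made from polyadenylated RNA, and how well these transcripts were captured was not measured. Lists too small for camera were the 3 platelet and erythroid genes, of which none passed, and the 4 neutrophil and mast cell genes, of which CLC rose and KIT fell (2 and 2 adjusted over the list alone).

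The tumour marker list was lower on balance with BiTE-sialidase, with a list median log2 fold change of −1.14. Not all of its members fell, and the list lost its call with an estimated correlation. The tables argue against the scaling of the libraries, since the list median lay between −1.22 and −0.97 under equal totals, quantile normalisation and TMM. Less RNA carried over from MDA-MB-231 cells, which sorting for CD3 was meant to remove, may account for it: KRT19 went from 58.9 ± 19.5 to 11.8 ± 9.66 normalised counts and KRT8 from 23.4 ± 6.28 to 6.71 ± 4.38. However KRT18, another keratin of the line, was at 50.4 ± 15.2 and 55.6 ± 3.53 (log2 fold change 0.18, 95% bounds −0.37 to 0.73), so carried-over RNA and a change within T cells cannot be told apart. None of the 37 measured members was on another list, how many of them T cells also express was not measured, and an effect of the sialidase on the T cells stayed open as untested.

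Heat shock genes rose together, and handling that differed between libraries could do the same. With HSPA1A as a covariate, the group difference in the mean of 20 other members went from 0.69 (SE 0.11) to 0.19 (SE 0.05), a range of 0.093 to 0.294 at 2 standard errors. Of these members 11 were still past the threshold. HSPA1A lay between 676 and 1546 normalised counts in BiTE and between 3182 and 6198 in BiTE-sialidase libraries, and rose with the replicate number within each group. The mean log2 level of the heat shock list also rose with the replicate number within each group. It lay between 11.36 and 11.61 in BiTE and between 12.02 and 12.28 in BiTE-sialidase libraries. The groups were thus further apart than the libraries within them. HSPA1A itself separated the groups, so a handling gradient and a response to the sialidase cannot be told apart.

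GZMB rose 3.08-fold while PRF1 did not pass. More CD8 T cells in the sort are argued against by CD8A at −0.39 and CD8B at −0.49, both lower, as far as these transcripts follow cell numbers. CD3G, a chain of the protein sorted for, was also lower, at −0.50, while CD3D (−0.10) and CD3E (−0.05) did not pass. More natural killer cells, which lack CD3 and which the sort was meant to remove, are argued against by their marker list, whose 75th percentile was 0.16 and whose highest member was at 0.74, below GZMB at 1.62. An effect of the sialidase on T cells and a shift within CD4 T cells stayed open as untested. Bulk libraries give no level per cell, and a measurement of GZMB in CD4 and CD8 T cells apart would show in which cells it rose.

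The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 1866 higher and 1383 lower genes with limma, and the highest count in another split was 0, with at most 701 genes at an unadjusted p under 0.05 against 5152 in the real one, so 1 of 10 splits gave as many in each direction. For gene lists the real split gave 20 and the others between 5 and 13, again 1 of 10. Camera with the preset correlation thus passed lists even in splits with 0 genes called. Each of those splits mixed the groups unevenly, however, so part of the group difference stayed between its sides. The rest added to the spread within them. The splits therefore cannot show how often camera passes a list that does not differ. A call with the preset correlation alone remains tentative, since 0 lists passed with an estimated correlation.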
